A study of Gallus gallus with 2 samples.

How the data were processed

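Total RNA of 6C2 cells, a chicken erythroleukemia line, was sequenced in 2 samples. Per the labels' protocols, the RNA was treated with DNase and depleted of ribosomal RNA with RiboMinus probes. It was then fragmented with RNase III and made into libraries with the SOLiD Total RNA-Seq kit, and 2 libraries were pooled per lane. No selection for poly(A) tails was described, so small RNAs and other RNAs without tails could enter the libraries. RNase III cuts double-stranded RNA and size selection follows it, so RNAs that are short or folded can be over- or underrepresented. The aligner, the counting tool, the genome build and the annotation release are not given in the sources used here. Coordinates are therefore given as deposited, without a build.

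The authors deposited 1 table for the series with a read count and an RPKM value per gene and sample. Per the file headers, the deposited counts and the deposited RPKM values stand side by side with the gene's identifier, position, strand, length and symbol. Every RPKM value could be recomputed, within 0.006 plus rounding, as the count divided by the gene length and by 1 library total per sample. These totals lay 0.881% under the sum of the counts in replicate 1 and 0.86% under it in replicate 2. RPKM divides by the length of a gene model, so short models reach high values from few reads, and a share of reads taken by small RNAs lowers the RPKM of all other genes. How reads that match several genes were counted is not given in the sources used here, so values of near-identical copies and of overlapping genes are uncertain.

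The table held 17934 genes. Of these, 1470 on unplaced contigs had no symbol and 0 reads in both samples, and they were left out after the table was examined. The 16464 genes analysed included 13086 with a name beyond an identifier. Positions appeared to count from 1, since 10 of 36 neighbouring mitochondrial genes started right after the end of the one before. The listed length of all 739 small RNAs was the end minus the start. The 18 gene lists were fixed before the data were examined. Their members were matched by symbol and, where a symbol had no match, through unambiguous synonyms in the RefSeq gene table of assembly GRCg7b. Where a symbol had several models, the longest was used.

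The measure was the deposited RPKM, on a scale of log2(RPKM + 1). The plan had been written for RPKM values, and the counts in the table were used for depth, for limits at 0 reads and for the comparison of the samples with sampling noise. With 1 group there was no test between groups. A gene was called detected at an RPKM of at least 1 in both samples. A list was said to stand apart when its median lay at or above the 97.5th or at or below the 2.5th percentile of 10000 random lists of the same size drawn from named genes. The 5 immune lists were compared with 51 pooled markers of T cells, B cells, macrophages and granulocytes by a 2-sided permutation test of the difference in mean with 100000 resamples, or by an exact permutation test for a list of fewer than 10 members. CSF3R, which is both in the cytokine list and among the granulocyte markers, was left out of both sides, which left 31 members against 50 markers. P-values had Benjamini-Hochberg adjustment over the 5 lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

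The genes named were chosen by a rule fixed before the data were examined: the 20 named genes of highest mean RPKM, the 4 highest members of each list and its first 2 members under 1 in both samples, the 5 genes with the largest difference each way among those of mean RPKM at least 5, and a fixed set that included EGFR, THRB, ERBB4, MYB, KIT, SPI1, IRF1, IRF8, CIITA, BRD2, TLR3, B2M, BF2, CTCF, CA2 and TFRC. The highest long genes, B-F, GNB2L1, the microRNAs, the hosts of small nucleolar RNAs, and the neighbours of EGFR and of the ribosomal RNA on chromosome 1 were named after their values were seen, as were the longer CAD model and, beside the counts they change, TREM-A1 and COL1A2. Some genes that the rule takes are not reported here.

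The steps were tested on simulated data made from the 13086 named genes. For lists of 15 genes, the percentile called 2% of lists high with no shift. With shifts of 1, 2 and 3 on the log2 scale, it called 22%, 68% and 76% high. Only calls at the high end were counted, and only upward shifts were added. The 2% is thus a rate of false calls at the high end alone, and calls at the low end were not tested on simulated data. The permutation test called 5%, 42% and 88% at shifts of 0, 1 and 2. Both of its simulated lists were drawn from all named genes, and p-values were not adjusted. List sizes and the spread of the markers differed from those of the immune comparisons, so these rates are not the power of those tests. Limits at 0 reads are the RPKM of 3 reads in that sample and cover counting error only, since reads amplified by PCR are not independent molecules. A read on a model of 1 kb was worth 0.0252 RPKM in replicate 1 and 0.0329 in replicate 2.

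Alternatives covered the detection threshold, the scaling, the pseudocount, filters on low values, the background of the random lists, the marker lists, and leaving out each replicate. Alternatives added after the data were examined were the use of all genes of the table, a background without small RNAs, lists without members matched through a synonym, chromosome shares and top shares over longer models, and EGFR, THRB and ERBB4 without each replicate. The values of EGFR, THRB and ERBB4 are given per sample or as mean ± SD, and a value of 1 of 2 samples cannot lie outside their SD, so leaving out a replicate tests nothing there.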

Results

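Gene expression was measured by total RNA sequencing in 6C2 cells, a transformed chicken line of red cell precursors that the labels place at the erythroid colony-forming unit stage, cycling and arrested before terminal differentiation. The series held 1 group of 2 samples, called replicate 1 and replicate 2 here, and no second group. The gene table held 40064443 reads for replicate 1 and 30668939 reads for replicate 2. Values below are RPKM as mean ± SD of the 2 samples (n = 2) unless values of both samples are given. The labels do not say whether the samples came from separate cultures, so the spread between them may be technical. The title of the series names immune-related genes in red cells as its subject, and the lists of genes below were built around that question.

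Small RNAs were the largest of the gene classes counted in 6C2 cells. They made up 33.6% ± 1.04 of the reads (SD, n = 2), with small nucleolar and Cajal body RNAs, which guide the modification or processing of other RNAs, at 24.4% ± 1.28. The 7SK RNA, which holds the elongation factor P-TEFb in check, took 6.96% ± 0.55 of the reads, ribosomal protein genes took 10.1% ± 0.94 and mitochondrial genes 5.73% ± 0.43. Of the 20 named genes of highest mean RPKM, every one was a small RNA, led by 7SK at 213523 ± 16751, the U3 small nucleolar RNA at 160330 ± 25150 and SNORA73 at 78843 ± 1551. SNORD65, SNORD100, SNORD47 and SNORD61 followed. A Y RNA and the RNA of nuclear RNase P also stood among these 20. Among named nuclear genes with models of at least 200 bp that were no small RNA, a group chosen after the values were seen, the elongation factor gene EEF1A led with 11221 ± 692, followed by RPS3A at 7394 ± 209 and RPS12 at 7048 ± 589.9. The 10 highest genes held 28.4% of the summed RPKM of replicate 1 and 27.7% of that of replicate 2, and the 100 highest held 76.3% and 77.8%. Of the reads, the 10 highest genes by reads held 20.5% and 20.1%, and the 100 highest 44.6% and 44.3%. Without mitochondrial genes and small RNAs the 10 highest genes held 14.7% of the summed RPKM on average, and the 100 highest 45.9%. Among all models of at least 200 bp these shares were 57.1% and 74.9%. That set was chosen by length alone, so it still held 7SK, U3, SNORA73 and the longer mitochondrial genes.

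A total of 8656 of the 16464 analysed genes, 52.6%, reached an RPKM of 1 in both samples. Of these, 4916 reached 10 and 797 reached 100. Among the 13086 genes with a name, 7900 were detected at an RPKM of 1, or 60.4%. Ribosomal protein genes were detected for 65 of 66 symbols, mitochondrial genes for 37 of 37, histone genes for 24 of 35, and small RNAs for 342 of 739.

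Expression in the 2 samples was close for most genes. Pearson's r of log2(RPKM + 1) across the 16464 genes was 0.996 and Spearman's rho was 0.961. These are descriptions across genes, which are not independent replicates. Of the 8859 genes with a mean RPKM of at least 1, 90.2% lay within 1.5-fold and 98.0% within 2-fold of each other in the 2 samples. The samples differed by more than counting noise, with a chi-square of 54.7 per degree of freedom over 10517 degrees of freedom, so they were not treated as the same library deposited again. This does not show that they came from separate cultures or RNA preparations. Of 6766 genes with a mean RPKM of at least 5, 5 were at least 3-fold higher in replicate 1 and 0 were at least 3-fold higher in replicate 2. At 2-fold or more these numbers were 19 and 10. With 1 sample on each side, these differences have no replicate check and no p-value.

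On the log2(RPKM + 1) scale, the largest difference among these genes was 2.69, at ENSGALG00000021752. This gene without a symbol lies on chromosome 1 from 104452569 to 104460312, with an RPKM of 1442 in replicate 1 and 222.4 in replicate 2. The other 4 that were at least 3-fold higher in replicate 1 were short models without a symbol, led by ENSGALG00000022970 at 12.1 and 1.39. As a plain ratio of RPKM, the difference at ENSGALG00000022970 was the larger. The 5 genes that lay lowest in replicate 1 were a 5S ribosomal RNA on chromosome 2 with 4597 and 13753, a U5 spliceosomal RNA with 169 and 423, a 220 bp model listed as CAD, a gene of pyrimidine synthesis, with 6.18 and 16.4, ENSGALG00000022847 with 98.1 and 217, and gga-mir-1804 with 8.29 and 18.9. The CAD model ENSGALG00000016521 held 54 and 110 reads, and a longer model of the same symbol, of 1344 bp, stood at 6.89 and 12.5. Models under 200 bp differed 2-fold or more in 5.18% of 463 cases, and longer models in 0.0793% of 6303 cases. Among genes with at least 1000 reads in each sample, the SD of the log2 ratio was 0.39 for models under 200 bp and 0.20 for models of 2000 bp or more.

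**Figure D1:**
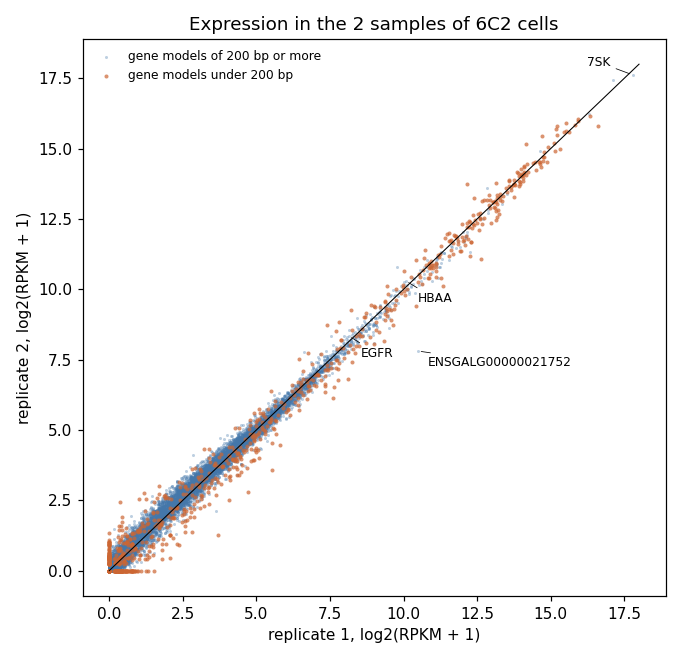
Each point is 1 of the 16464 genes, with log2(RPKM + 1) in replicate 1 on the x axis and in replicate 2 on the y axis, and the line marks equal values. Models under 200 bp are orange and longer models blue, and the gene farthest from the line, ENSGALG00000021752, lies 2.69 log2 units toward replicate 1.

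Among the 5 globin genes measured, HBAA was the highest. The alpha globin gene HBAA stood at 1168 ± 119.7, the alpha-D gene HBAD at 76.7 ± 1.68 and the embryonic gene HBZ at 14.1 ± 2.93. HBAA was 15.2 times HBAD, with 13.9 in replicate 1 and 16.6 in replicate 2. HBG2 and HBE, the globin genes measured on chromosome 1, were close to 0. HBG2 had 2 reads in replicate 1 and 0 in replicate 2, and HBE had 0 reads in both, which allows up to 0.143 RPKM in replicate 1 and 0.187 in replicate 2. HBBA, HBB and the other beta globin symbols of the list were not analysed here, so these 2 genes do not give the level of the beta family. Globins as a list of 5 lay at the 84.6th percentile of random lists and did not stand apart. The 3 members of mean RPKM at least 0.1 lay at 98.0, against a background limited in the same way. That limit took out HBG2 and HBE by the same value that was then ranked, so this does not show that globins as a list stood apart.

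Genes of heme synthesis and iron handling were high, with 17 of 17 detected and the median of the list at the 99.98th percentile of 10000 random lists of the same size. The ferritin heavy chain gene FTH1, which stores iron, reached 1876 ± 103, and the transferrin receptor gene TFRC, which takes iron up, reached 281 ± 24.0. ABCB10, a mitochondrial transporter of the red cell lineage, stood at 105 ± 8.70. Red cell membrane and late red cell genes were detected for 14 of 16 members and lay at the 97.58th percentile, just past the threshold. The percentile fell to 97.2 without replicate 2 and to 91.5 without the member matched through a synonym, which ended the call. That member was the linker histone gene listed as H1F0, which carries H5 among its synonyms and stood at 274 ± 9.55. BPGM, which makes the red cell metabolite 2,3-bisphosphoglycerate, reached 249 ± 3.59, the blood group gene KEL 64.3 ± 3.10, the spectrin gene SPTAN1 63.4 ± 5.58 and the carbonic anhydrase gene CA2 24.0 ± 1.51. The water channel gene AQP1 was under 1, at 0.06 and 0.11.

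Erythroid regulators were detected for 12 of 13 members and progenitor regulators for 10 of 15, and neither list stood apart, at the 81.9th and 45.3rd percentile. Limited to a mean RPKM of at least 0.1, erythroid regulators lay at 55.3 and progenitor regulators at 23.4. BACH1, a heme-sensing repressor, stood at 101 ± 5.46, the repressor gene GFI1B at 68.1 ± 8.55, STAT5B at 56.9 ± 8.74 and LMO2 at 52.6 ± 2.45. KLF3 lay at 0.74 and 0.81. Among regulators of progenitors, MYB reached 71.6 ± 9.77, GATA2 46.4 ± 8.75, MYC 37.7 ± 10.9 and FLI1 26.5 ± 2.86. The stem cell factor receptor gene KIT was at 0.30 and 0.41, the progenitor surface marker CD34 at 0.08 in both samples, and SPI1, which encodes the myeloid regulator PU.1, at 0.20 and 0.10. GATA1, TAL1, KLF1, ALAS2 and SLC4A1 were not analysed here.

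Cell cycle genes gave the highest percentile of the 18 lists, at 100, with 27 of 28 members detected. Heme and iron genes, at 99.98, also reached 100 under several alternatives, such as a length-matched background. Their median was 39.5 RPKM against 38.0 for cell cycle genes, so the order of these lists is not settled. The replication clamp gene PCNA stood at 456 ± 52.9, the mitotic cyclin gene CCNB2 at 233 ± 5.08, the mitotic kinase gene CDC2 at 201 ± 6.49 and the ribonucleotide reductase gene RRM1 at 117 ± 2.61. The cell cycle inhibitor gene CDKN1A had 0 reads in both samples on a model of 169 bp, which allows up to 0.447 and 0.584 RPKM. Chromatin regulators were detected for 23 of 23 members, at the 97.1st percentile and under the threshold. Without replicate 1 the percentile was 98.6, past it, and with members and background limited to a mean RPKM of at least 0.1 it was 85.6. H3-IX reached 339.7 ± 16.3, the histone variant gene H2AFZ 187 ± 3.42 and the deacetylase genes HDAC2 and HDAC1 80.0 ± 2.72 and 55.1 ± 2.29. The insulator protein gene CTCF stood at 12.8 and 11.3 and the bromodomain gene BRD2, which lies within the MHC, at 13.4 ± 3.46.

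Immune genes of several pathways were transcribed in 6C2 cells while markers of immune cell lineages were near 0. Of the 51 pooled markers of T cells, B cells, macrophages and granulocytes, 3 were detected, and their median was 0.07 RPKM. Genes of the MHC class I pathway stood 3.03 above these markers in mean log2(RPKM + 1), with 8 of 10 detected (2-sided permutation test, p = 5e-05, Benjamini-Hochberg adjusted p = 8.3e-05 over the 5 lists). Interferon response and cytosolic sensing genes stood 2.16 above them, with 22 of 33 detected and 33 of 33 above the median marker, and Toll-like receptor and NF-kB genes 2.34 above them, with 21 of 29 detected. Both of these gave a permutation p of 1e-05, the smallest the 100000 resamples can give, and an adjusted p of 2.5e-05. Cytokines, chemokines and their receptors stood 0.84 above the markers (permutation p = 0.0115, adjusted p = 0.0144), tested with 31 members against 50 markers because CSF3R stood in both. Of the 32 measured members, 12 were detected. The 7 MHC class II genes were 0.87 above them, which did not pass (exact permutation p = 0.0702, adjusted p = 0.0702). With markers of thrombocytes and fibroblasts pooled in, the cytokine difference was 0.58 and no longer passed (permutation test, adjusted p = 0.128). The class II difference passed with a pseudocount of 0.1 (exact permutation test, adjusted p = 0.0215) and for medians (permutation test, adjusted p = 0.0018). The sizes depended on the scale: with a pseudocount of 0.1 the differences were 5.02 for class I, 3.96 for interferon genes, 4.04 for Toll-like receptor genes, 2.10 for class II and 1.72 for cytokines, and between medians the cytokine difference was 0.16. These tests run across genes, which are not independent replicates. The bar was low, since the markers had a median of 0.098 in log2(RPKM + 1). Random lists of named genes typically had 2.30 at the size of the class I list and 2.39 at that of the interferon list. Lists of ordinary genes would thus tend to stand above the markers, so a low p-value here does not single out immune genes.

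Against random lists of named genes, none of the immune lists stood high. MHC class I lay at the 58.2nd percentile, MHC class II at the 27.4th, interferon response and sensing at the 51.1st and Toll-like receptor and NF-kB signalling at the 77.7th, so none of these 4 stood apart. With members and background limited to a mean RPKM of at least 0.1, class I lay at 25.2, class II at 10.6 and interferon genes at 11.6, still without standing apart. Cytokines, chemokines and their receptors stood low, at the 0.49th percentile.

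In the MHC class I pathway, B2M, the light chain of class I molecules, reached 318 ± 18.5, and PDIA3, a chaperone of peptide loading, 176 ± 10.2. The class I heavy chain gene BF2 stood at 22.2 ± 0.516 and NLRC5, a transactivator of class I genes, at 20.9 ± 4.48. B2M was 14.3 times BF2, with 13.5 in replicate 1 and 15.2 in replicate 2. The peptide transporter gene TAP1 was at 0.55 and 0.85, and the class I-like gene YFV at 0.16 and 0.21. Reads of class I genes may be shared between near-identical copies, so the values of BF2 and of its neighbour B-F, at 18.4 and 17.5, are uncertain as a split. The lists of class I and class II genes were not tested against each other. In the class II list, the thiol reductase gene IFI30 stood at 19.7 ± 2.70, DMA at 1.87 ± 0.18 and the protease gene CTSS at 1.48 ± 0.467, while the invariant chain gene, listed as II, was at 1.07 and 1.14. The class II beta chain gene BLB1 had 2 reads in each sample, or 0.05 and 0.07 RPKM, DMB2 was at 0.46 and 0.84, and the class II transactivator gene CIITA was at 0.06 and 0.12. On chromosome 16, BLB1 (69833 to 71353) lay beside BRD2 (72250 to 81313), and BRD2 stood at 10.99 and 15.88 RPKM. BLB2 was not analysed here.

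**Figure D2:**
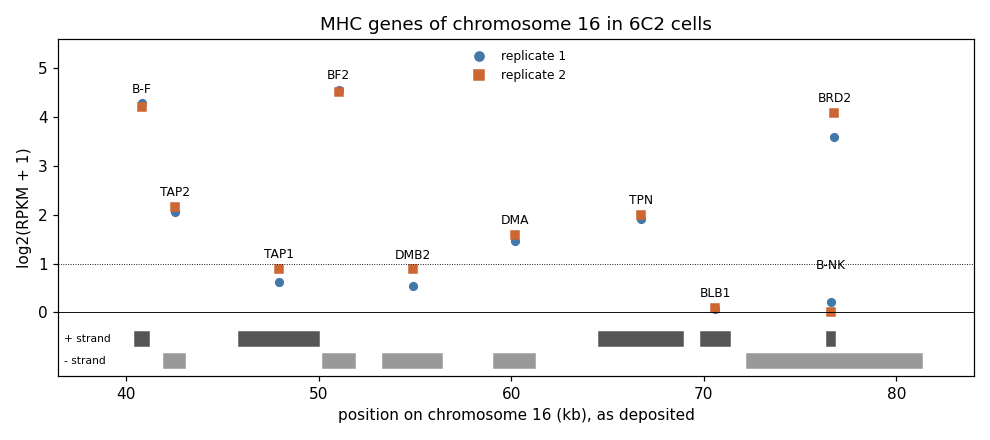
Named genes of the MHC on chromosome 16 are drawn to scale by position in kb, with boxes for the strand and points for log2(RPKM + 1) in replicate 1 and replicate 2, and the dotted line marks an RPKM of 1. BF2 and B-F lie near 20 RPKM, at 22.6 and 21.9 for BF2, and BLB1 lies at 0.05 and 0.07 beside BRD2 at 10.99 and 15.88.

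Receptor genes and a signalling kinase gene were among the 4 highest members of the interferon list. The interferon gamma receptor gene IFNGR1 reached 76.8 ± 6.05, the kinase gene JAK1 57.0 and 48.2, IFI27L2 52.3 ± 7.29 and the type I interferon receptor gene IFNAR2 39.4 ± 3.49. IRF8 was at 9.13 and 11.4, whereas IRF1 was at 0.94 and 0.99 and the antiviral gene MX at 0.33 and 0.36. In the Toll-like receptor and NF-kB list, the adaptor kinase genes IRAK4 and IRAK2 stood at 52.7 ± 0.120 and 33.3 ± 0.467, MAP3K7 at 47.3 ± 0.573 and the sensor gene NOD1 at 34.6 ± 0.544. TLR3, a sensor of double-stranded RNA, stood at 4.65 ± 0.283. TLR2-1 was at 0.02 and 0.05, and TLR2-2 had 0 reads in both samples, which allows up to 0.0343 and 0.0448 RPKM. The detected members of the cytokine list were led by the receptor genes IL17RA at 61.4 ± 0.488 and IL10R2 at 38.3 ± 1.92. The death ligand gene TNFSF10 at 13.9 ± 0.424 and the receptor gene IL4R at 10.6 ± 0.460 followed. The cytokine genes IL6 and CCL4 were under 0.2 in both samples.

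Markers of other cell types stood low, at the 0.05th percentile for T cells, the 0.11th for B cells, the 0.42nd for macrophages, the 0.07th for granulocytes and the 1.57th for fibroblasts and stroma. The macrophage list no longer stood apart, at 3.85, when members and background were limited to a mean RPKM of at least 0.1, which left 5 members. The detected members were few. Of 16 T cell markers, CD3E was detected, at 2.42 and 2.91, while CD3D was at 0.57 and 0.78 and CD247 at 0.24 and 0.31. Of 14 B cell markers, the kinase gene BTK was detected, at 108 ± 9.35, while BLNK was at 0.24 and 0.15 and CD79B at 0.03 and 0.04. Of 13 macrophage markers, the lysosomal protease gene CTSB was detected, at 116 ± 4.99, while CSF1R was at 0.05 and 0.09 and CD14 at 0.05 and 0.07. Without replicate 2, 2 macrophage markers passed, TREM-A1 being at 1.02 and 0.72. Of 13 fibroblast markers, SPARC was detected, at 101 ± 17.7, and without replicate 1 COL1A2, at 0.88 and 1.57, passed as well. None of the 8 granulocyte markers was detected. Thrombocyte markers were detected for 5 of 11 members and did not stand apart, at the 8.32nd percentile, or 33.9 when limited to a mean RPKM of at least 0.1. The tubulin gene TUBB1 reached 82.1 ± 4.40, GP1BB 12.6 ± 1.22, TBXAS1 13.1 and 10.85 and GP9 6.22 and 5.77, while GP1BA was at 0.04 and 0.10.

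**Figure D3:**
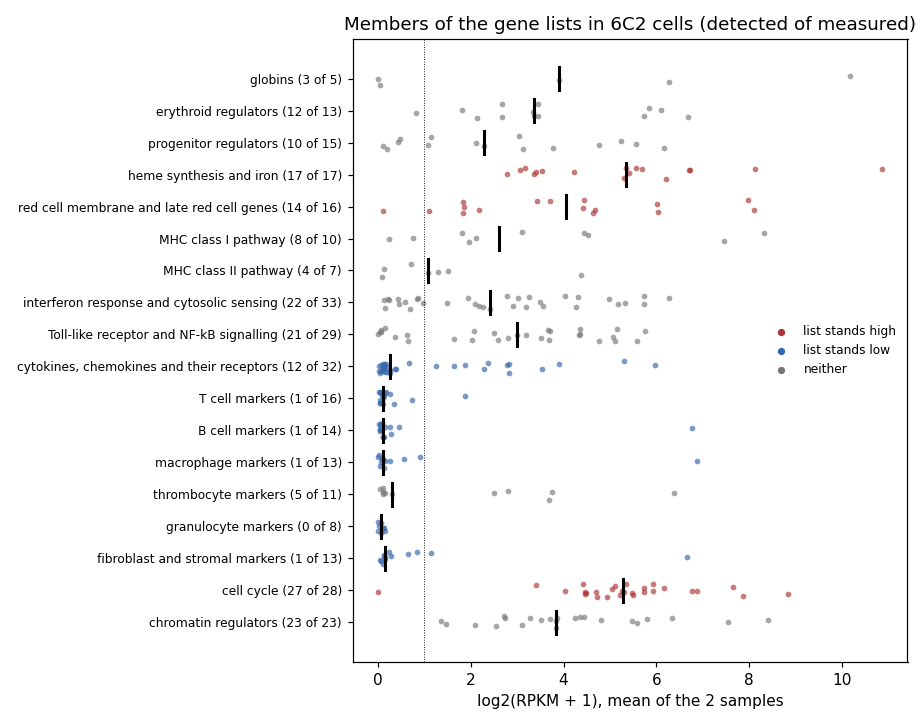
Each point is 1 measured member of a list, placed on the x axis by log2(RPKM + 1) as the mean of the 2 samples, with the list's median as a black bar, an RPKM of 1 as the dotted line and the detected of measured members beside each name. Heme and iron, red cell membrane and cell cycle lists stand high (red), and cytokines and 5 of the 6 lists of cell type markers stand low (blue).

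EGFR, the cellular counterpart of the oncogene erbB of avian erythroblastosis virus, was among the higher genes at 302 ± 28.9 RPKM. Its 97069 and 85106 reads lay on a model of 8678 bp on chromosome 2 from 51962655 to 52111376. The related receptor gene ERBB4 stood at 10.7 ± 3.05, so that EGFR was 28.3 times as high, with 33.1 in replicate 1 and 25.2 in replicate 2. EGFR ranked 157th among 12293 named nuclear genes with models of at least 200 bp that were no small RNA. The thyroid hormone receptor gene THRB was at 5.51 and 8.66. ERBB2, ERBB3 and THRA, the counterpart of the viral erbA, were not analysed here.

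Detection was similar across the larger classes of chromosomes. Genes at an RPKM of 1 in both samples made up 52.0% of 7517 genes on macrochromosomes 1 to 5, 51.9% of 2764 on chromosomes 6 to 10 and 53.0% of 5277 on microchromosomes, which are small and gene-rich. The Z chromosome had 56.5% of 793 genes detected. Chromosome 16, which carries the MHC, had 43.1% of 72 genes detected, or 12 of 27 among named genes with models of at least 200 bp that were no small RNA, where macrochromosomes had 59.9% and microchromosomes 63.2%. These shares were not tested.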

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

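Of 168 alternatives for list percentiles and immune lists, 157 kept the main call and 0 reversed it. A list whose percentile stood neither high nor low could not be reversed. Of 109 alternatives for counts, 102 lay within 1.5 times the main count. A further 23, for agreement, top shares and chromosome shares, were held against a spread, and 0 of them stayed within it. For agreement the spread was a 95% interval of r that takes genes as independent. For shares it was the SD of the 2 samples, which was 0 on chromosome 16. These spreads were narrow, so lying outside them does not mean a large change. Alternatives over all genes of the table, longer models only, and lists without synonym matches were chosen after the data were examined. Detected genes ranged from 7298 after rescaling to TPM to 9281 at an RPKM of 0.5, and histone genes from 18 at 2 to 29 at 0.5. Pearson's r was 0.989 with a pseudocount of 0.1, 0.965 with 0.01, 0.993 among genes of mean RPKM at least 1 and 0.996 over all genes of the table. The 5 genes with a 3-fold difference became 2 at a mean RPKM of at least 20. The 10 and 100 highest genes held 14.7% and 45.9% of the RPKM without mitochondrial genes and small RNAs. They held 57.1% and 74.9% among all models of at least 200 bp, where 7SK, U3 and SNORA73 remained. Detected members moved at an RPKM of 2 to 1 for MHC class II, and at 0.5 to 2 for T cells, 2 for macrophages and 4 for fibroblasts. Leaving out a replicate gave 1 to 2 macrophage and 1 to 2 fibroblast markers.

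The red cell membrane list lost its call against genes above 0 (97.3), with low genes left out (96.0), without the synonym (91.5) and without replicate 2 (97.2, against 97.57 without replicate 1). Macrophage markers lost theirs with low genes left out (3.85). Globins passed with low genes left out (98.0), where 3 members remained. Chromatin regulators passed with a length-matched background (97.7) and without replicate 1 (98.6, against 96.3 without replicate 2). With low genes left out they lay at 85.6. MHC class II passed with a pseudocount of 0.1 (2.10) and for medians (0.98), and cytokines did not pass with more markers pooled in (0.58). Detection at 0.5, at 2 and among named longer models was 55.4%, 48.1% and 59.9% on macrochromosomes, 56.0%, 48.0% and 60.2% on chromosomes 6 to 10, 57.4%, 48.0% and 63.2% on microchromosomes, 45.8%, 36.1% and 44.4% on chromosome 16, and 59.3%, 52.0% and 64.5% on Z. The cause was not tested where the alternative's construction does not give it. Agreement and differences need both samples, so neither could be computed without a replicate. Depth limited statements on genes under about 0.1 RPKM, where 3 reads on a model of 1 kb are 0.0755 and 0.0987 RPKM.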

Other observations

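Small nucleolar RNAs lay mostly inside highly expressed genes. Of 200 small nucleolar and Cajal body RNAs, 154 lay inside a longer gene on the same strand, in 89 host genes of which 22 encode ribosomal proteins. Hosts were assigned by position alone, so it was not shown that each RNA is made from its host. The median host stood at 109 RPKM, against 4.50 for all named nuclear genes with models of at least 200 bp, and 47 of the 89 hosts reached 100 RPKM. On chromosome 16, SNORD95, at 14862 and 18323 RPKM, lay inside GNB2L1, which encodes the ribosome-bound scaffold protein RACK1 and stood at 389 and 324.

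Of 432 models of microRNA precursors, 96 were detected, and they were looked at after the values were seen. Counts per model do not tell a precursor from a longer transcript or a mature RNA of the same sequence. The model of miR-155, which the immune system also uses, was the highest at 1328 ± 151. It was followed by gga-mir-103-2 at 496 ± 58.7, gga-let-7f at 294 ± 59.3, gga-mir-20b at 247 ± 43.0 and gga-mir-92 at 243 ± 3.10. The models of miR-451 and miR-144, which are known from later red cells, had 2 and 0 reads and 0 and 0 reads in replicates 1 and 2. For gga-mir-144, 0 reads allow up to 0.899 and 1.17 RPKM.

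The region of chromosome 1 that held the largest difference between the samples on the log2(RPKM + 1) scale also held a 5.8S ribosomal RNA. ENSGALG00000021752, at 42033 and 4963 reads, lay next to ENSGALG00000022847, at 1862 and 3149 reads, whose span from 104461784 to 104506283 held the 5.8S gene at 104486666 to 104486818. The 5.8S gene itself had 677 and 393 reads, or 112 and 85.0 RPKM. Of 7 detected 5S ribosomal RNAs, 1 was higher in replicate 1. No explanation was tested for these differences.

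Of the tests below, the comparison of EGFR with ERBB4 was chosen after the result was seen. Ribosomal protein genes were higher in replicate 1 for 52 of 65 detected members, with a median log2 ratio of 0.15 where other detected named genes had -0.06. Reads of small nucleolar RNAs inside these genes are argued against as the whole cause, since the 43 members without such an RNA still lay 0.21 above other named genes (resampled 95% interval 0.13 to 0.34). Gene length and expression level may contribute and stay open. Against 325 other genes chosen for the nearest length and level the class lay 0.074 higher (0.03 to 0.17), and those genes themselves had a median of 0.08, but their median level was 212 RPKM against 1589 for the class, so the match was incomplete. With 1 group, no biological explanation was tested.

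The height of EGFR over ERBB4 is not accounted for by overlapping genes, because 0 other genes overlapped it and they held 0% of its reads. High expression of the whole neighbourhood stays open, since the 6 named genes within 500 kb had a median of 0.0954 times EGFR, below the 0.1 set beforehand by less than their spread, and reached 286 RPKM at SEC61G. Reads from a viral copy of erbB could have been counted at EGFR, and the ratio of 28.3 to ERBB4 is what either a viral copy or a highly expressed cellular gene would give, so these cannot be told apart from counts per gene. The position of reads along the gene, not used here, would bear on it.

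A candidate explanation for the levels of small nucleolar RNAs is the level of the host gene. Across the 89 hosts, the mean RPKM of the RNAs inside a gene and that of the gene had a Spearman rho of 0.445 (permutation p = 3e-05) and a Pearson r on the log2 scale of 0.446, across genes that are not independent replicates. Counting of all the same reads at the host as well is argued against for 60 of the 89 hosts. These held fewer reads in both samples than the small nucleolar RNAs inside them. For the other hosts, and for counting of a part of the reads, this comparison cannot tell. Whether the relation comes from shared transcription was not tested.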
